A study of Homo sapiens with 6 samples.

How the data were processed

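LNCaP cells were transfected with a miR-106b precursor or a control precursor at 30 nM with a cationic lipid reagent and collected after 24 h, per the labels' protocols. Biotin-labelled cRNA from total RNA was hybridized to Affymetrix arrays. The values used are log2 expression per probe set as deposited by the authors, made with RMA per the submitters' processing notes, and its version is not given in the sources used here. RMA subtracts background, equalizes the distribution of every array and summarizes probes, so a shift shared by all genes cannot be seen in these values. All 6 value columns were assigned to a sample by name.

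The table held 15127 probe sets. Of these, 59 were manufacturer's controls, 13167 carried 1 gene symbol, 753 several and 1148 none in the platform annotation. Gene identifiers matched a current reference table of assembly GRCh38.p14, used for names only, for 13164 of the 13167, and 3 kept the annotation's symbol. For each gene the probe set with the highest mean over the 6 arrays was used, which gave 8739 genes, and 2926 of them had more than 1 probe set. Probe sets with several or no symbols were not named.

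The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and also with a change of at least 1.5-fold. The labels number the batches 1 to 3 and each holds 1 array per group under the same replicate number. Deviations from the group means correlated within batches at r = 0.507, 0.218 and 0.390 across genes. The highest values with an array of another batch were -0.186, 0.161 and 0.040. The numbers thus pair the arrays, least clearly in batch 2. The fit without a batch term was set as the main one before the data were examined because no protocol or design text puts the batch in a test, although the labels give it, and the value with the batch as a block is given where it changes a call or a count.

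Gene lists (23, fixed before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, which left 21, with adjustment over these lists. Camera was also run with the correlation estimated per list. That setting also bases its test on the far fewer residual degrees of freedom of the arrays. Fry was run as a second test. The genes named are the 12 per direction with the largest changes past the threshold and 1 sign in all batches, filled first from those past it with the block and then by the smallest p, up to 4 members per list with the smallest p, and a fixed set of regulators (among them CDKN1A, E2F1, BCL2L11, TGFBR2, RB1, RBL2 and MCM7). A few other genes and families were chosen after the values were seen and are said to be. The text names part of the genes the rule takes, and the alternatives were computed for all 111 of them and for the others named. Some members of the fixed set are not reported here. A planned test of seed sites in 3' untranslated regions was not run because no transcript sequences were used here.

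The code was tested on simulated data for this comparison, with 200 changed genes among 8739 in each of 10 simulations. Each gene's spread was drawn from limma's fitted prior. The fit without a block called 14.5% of genes changed by 0.5 (log2), 94.0% of those changed by 1 and 99.1% of those by 1.5. Of its calls 0.719% were false. With the block the shares were 44.2%, 98.7% and 100%, and 4.88% of the calls were false. This noise model replaced an earlier one after its output had been seen, because that one gave the genes too similar a spread. With the earlier one the shares were 14.9%, 93.0% and 99.2% without the block and 87.0%, 100% and 100% with it. Of the calls 0.217% and 7.18% were false. A list shifted by -0.3 was called in 10 of 10 simulations of independent genes. Each simulated change was the same in every batch, whereas the real differences varied between batches. The shares therefore test the code and are not detection rates for these data.

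Alternatives covered the block, each array and each batch left out, repeated quantile normalization, 2 centrings, 2 filters on dim probe sets, the mean over probe sets, variance models, thresholds and list tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.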

Results

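Gene expression was measured in LNCaP cells, an androgen-sensitive line derived from a human prostate cancer, 24 h after transfection with 30 nM of a precursor of the microRNA miR-106b or of a control precursor. The set held 6 arrays, 3 per group, and each of 3 batches contributed 1 array of each group. The labels give the replicates as separate batches and do not say whether the cultures were grown independently, so the p-values measure the spread between these samples. Median log2 expression over the non-control probe sets lay between 6.75 and 6.83 on every array, and any pair of arrays correlated across genes with Pearson's r between 0.988 and 0.996. Genes are not independent replicates in that correlation. The number of arrays limits the precision of every value given.

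The series title names focal adhesion in connection with the microRNA cluster that includes miR-106b, and the comparison asks which transcripts differ after the precursor is added. No single gene passed an adjusted p of 0.05 without a batch term. By camera at a preset correlation between genes, the lists of division cycle genes and of literature targets of the miR-106b seed family were lower after pre-miR-106b and the unfolded protein and integrated stress response list was higher. These calls were lost when the correlation was estimated from the data (adjusted p from 0.449 to 0.623). FYCO1, an adaptor that links autophagosomes and late endosomes to microtubule transport and a literature target of this seed family, was at 7.66 ± 0.16 in control cells and 6.36 ± 0.47 after pre-miR-106b (log2 mean ± SD, n = 3), a difference of -1.30 with a standard error of 0.21. KIF23, a kinesin of cytokinesis, differed by -1.06 (SE 0.15) and CENPQ, a centromere protein, by -1.09 (SE 0.14). CENPQ was dim, at 5.24 in control cells and 4.15 after pre-miR-106b, against a 25th percentile of 5.02 to 5.07 on the arrays. It was not tested once the dimmest 25% of probe sets were left out. OSBPL9, an oxysterol-binding-protein relative, differed by 0.89 (SE 0.11). Standard errors here and below come from the fit without a batch term unless the block is named.

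Over all 8739 genes, limma without a batch term called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.115. At an unadjusted p under 0.05 there were 982 genes, 516 higher and 466 lower after pre-miR-106b. Another split of the 6 arrays, which kept both arrays of batch 1 together, gave 948. Among other splits that part every batch pair the highest count was 374. With the batch as a block 8 genes passed, all by at least 1.5-fold. FYCO1, RNH1, CENPQ, KIF23, SLITRK3 and TMCC1 fell, each with an adjusted p of 0.0333 with the block, and OSBPL9 (0.0333) and S100P (0.0375) rose. RNH1, the ribonuclease inhibitor, differed by -1.10 (SE 0.19, or 0.12 with the block) and SLITRK3 by -0.85 (SE 0.15, or 0.10 with the block). TMCC1 differed by -0.84 (SE 0.15, or 0.09 with the block). S100P, a calcium-binding protein, differed by 0.83 (SE 0.16, or 0.10 with the block). All 8 genes moved the same way in each batch. Over all genes, 3351 (38.4%) had 1 sign in all 3 batches, against 25% expected by chance. Genes move together on an array, which widens the spread around 25%, and that spread was not computed.

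These counts depended on the batches used. With the block and without batch 1, 340 genes passed (156 higher, 184 lower), which included the 8 genes, whereas 0 passed without batch 2 and 6 without batch 3. The SD of the gene differences was 0.21 in batch 1, 0.27 in batch 2 and 0.30 in batch 3.

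**Figure D1:**
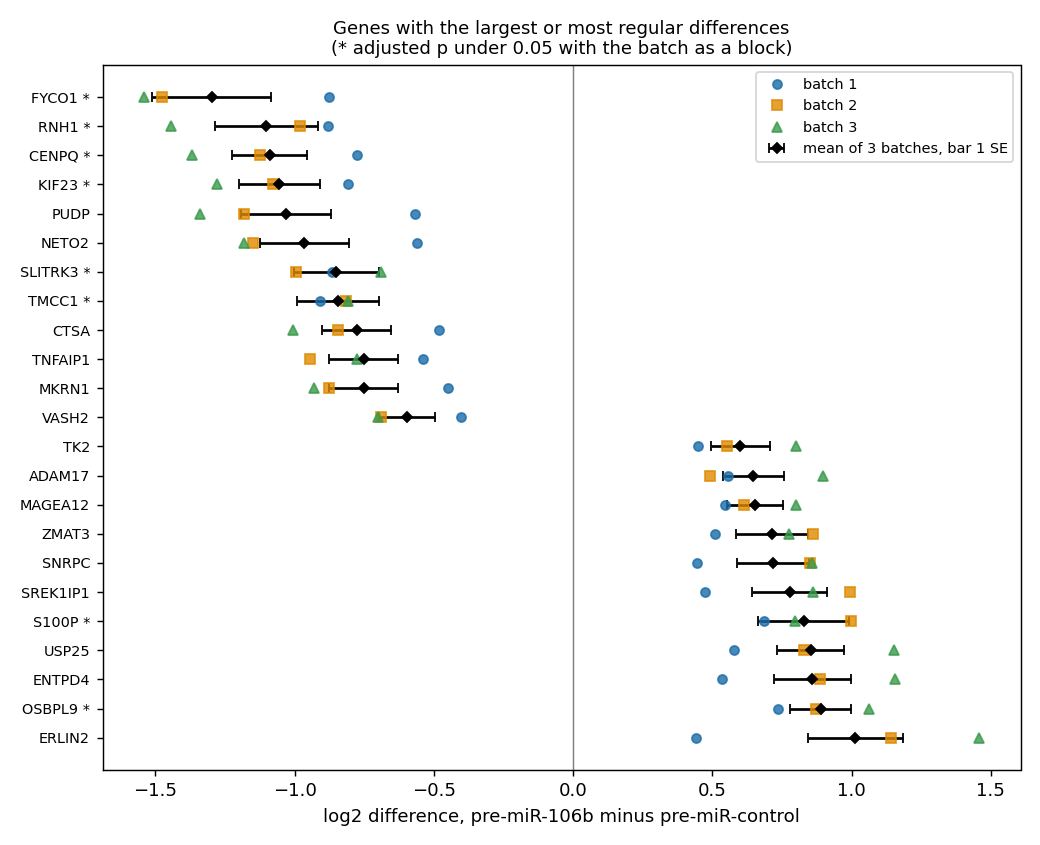
Differences between pre-miR-106b and pre-miR-control (horizontal axis, log2) for 23 of 24 genes with 1 sign in all batches, 8 past the threshold with the batch as a block and 16 chosen by the smallest p, with 1 marker per batch, a diamond for the mean of 3 batches and a bar of 1 standard error. DDX3Y, a Y-linked gene, is the one not drawn. Among those drawn FYCO1 lies lowest with a mean of -1.30 and ERLIN2 highest with 1.01. Asterisks mark the 8 genes past the threshold with the block, whereas the bars are standard errors of the fit without it.

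The other 16 genes with the smallest p and 1 sign in all batches did not pass with or without the block. On the lower side were PUDP (-1.03), NETO2 (-0.96), CTSA, the lysosomal protective protein cathepsin A (-0.78), TNFAIP1 (-0.75), MKRN1 (-0.75) and VASH2 (-0.60). MKRN1 has 2 probe sets that disagreed, with -0.75 for the brighter and 0.23 for the other. Dimmer probe sets also gave smaller values for TK2 (-0.01 and 0.19), ENTPD4 (0.15), ADAM17 (as low as 0.16) and TMCC1 (as small as -0.47). On the higher side were ERLIN2, a protein of endoplasmic reticulum degradation (1.01), DDX3Y (0.87), ENTPD4 (0.86), USP25 (0.85), SREK1IP1 (0.78), SNRPC (0.72), ZMAT3 (0.72), MAGEA12 (0.65), ADAM17 (0.65) and TK2 (0.60). VASH2 and SREK1IP1 were dim, with means over the arrays of 4.586 and 4.555 against a 25th percentile of 5.02 to 5.07.

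Of the 45 measured literature targets of the miR-106b seed family, 35 had lower and 10 higher values, with a median difference of -0.19. The list fell by camera (adjusted p = 5.93e-08), but with an estimated correlation the adjusted p was 0.449. Over all genes 0 members passed, and 1 (FYCO1) passed with the block. Adjusted over the list alone, 11 fell, 1 rose and 33 did not pass, and with the block 15 fell and 3 rose. TNFAIP1 (-0.75), E2F1, the transcription factor of S-phase entry (-0.77), CROT, a peroxisomal carnitine acyltransferase (-0.63) and CCND1, cyclin D1 (-0.39) were among those that fell. KLF9 (0.60, or 0.30 with mean probe sets) was the 1 that rose. It is a member outside the rule for named genes that was picked after its value was seen. CDKN1A, which encodes the cell-cycle inhibitor p21, differed by -0.72 (SE 0.25, or 0.13 with the block). Its adjusted p over the list alone was 0.0567, or 0.00452 with the block. The list's median was -0.11, -0.29 and -0.21 in batches 1, 2 and 3.

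The 43 measured G2/M genes had a median difference of -0.40, and 42 of them had lower values. The list fell by camera (adjusted p = 4.63e-19), with an adjusted p of 0.454 with an estimated correlation. Adjusted over the list alone, 19 genes fell and 24 did not pass, and with the block 23 fell. The 19 included KIF23, the mitotic kinase PLK1 (-0.58), the spindle factor TPX2 (-0.51) and cyclin B2, CCNB2 (-0.44). Over all genes 0 passed, and 1 with the block. The median was -0.03 in batch 1, -0.51 in batch 2 and -0.63 in batch 3.

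Among 43 measured G1/S and E2F target genes the median difference was -0.36, with 42 lower. The list fell by camera (adjusted p = 2.65e-12), with an adjusted p of 0.623 with an estimated correlation. E2F1 alone fell when adjusted over the list alone, and with the block 25 members fell and 1 rose. RRM2, a subunit of ribonucleotide reductase, had a difference of -1.06 (SE 0.33), or -0.51 with a second probe set nearly as bright (mean 10.04 against 10.05), CDK2 -0.75 (SE 0.20) and RFC2 -0.36 (SE 0.10). MCM7, a replication helicase subunit whose gene hosts the miR-106b cluster, differed by -0.56 (SE 0.22), passed over all genes neither without the block (adjusted p = 0.392) nor with it, and ranged from -0.790 to -0.286 over the alternative settings. Per batch the median was -0.04, -0.34 and -0.63. Batch 3 had the lowest median in this list and in the G2/M list. Its pre-miR-106b array also had the highest 3' to 5' ratios of beta-actin (0.73, log2) and GAPDH (0.30). A higher ratio is a sign of lower RNA integrity, and its part in the differences was not tested.

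The list of cyclin-dependent kinase inhibitors and the retinoblastoma family, with 14 measured members, fell by camera (median -0.20, adjusted p = 0.00741), with an adjusted p of 0.449 with an estimated correlation. PKMYT1 (-0.52), CDKN2D (-0.59) and WEE1 (-0.54) fell when adjusted over the list alone, 11 did not pass, and with the block 5 fell. PKMYT1 and WEE1 are kinases that hold back mitosis, and WEE1, CDKN1A and RBL2 also stand in the seed family list. RBL2 differed by -0.31 (SE 0.17) and RB1 by 0.02 (SE 0.11). Medians in the 3 batches were -0.08, -0.17 and -0.48, and with the block and without batch 3 the list's median was -0.05. Batch 3 is the one whose pre-miR-106b array had the highest 3' to 5' ratios.

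The unfolded protein and integrated stress response list rose, with 27 of 32 measured genes higher and a median difference of 0.26 (camera adjusted p = 2.19e-07, and adjusted p = 0.454 with an estimated correlation). Adjusted over the list alone, 10 genes rose and 22 did not pass, and with the block 14 rose and 1 fell. The glutathione-degrading enzyme CHAC1 (1.06, SE 0.21), the cystine transporter SLC7A11 (1.14, SE 0.25, and as low as 0.47 with a dimmer probe set), the pseudokinase TRIB3 (0.65, SE 0.16) and PSAT1, an enzyme of serine synthesis (0.62, SE 0.15), were among the 10. The median was 0.05 in batch 1, 0.32 in batch 2 and 0.37 in batch 3. A higher ratio of 3' to 5' probe sets is a sign of lower RNA integrity. For beta-actin the ratio was 0.37 and 0.24 (log2, control and pre-miR-106b) in batch 1, 0.56 and 0.52 in batch 2 and 0.46 and 0.73 in batch 3. That of GAPDH was 0.30 on the pre-miR-106b array of batch 3 and between 0.11 and 0.14 on the other 5.

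**Figure D2:**
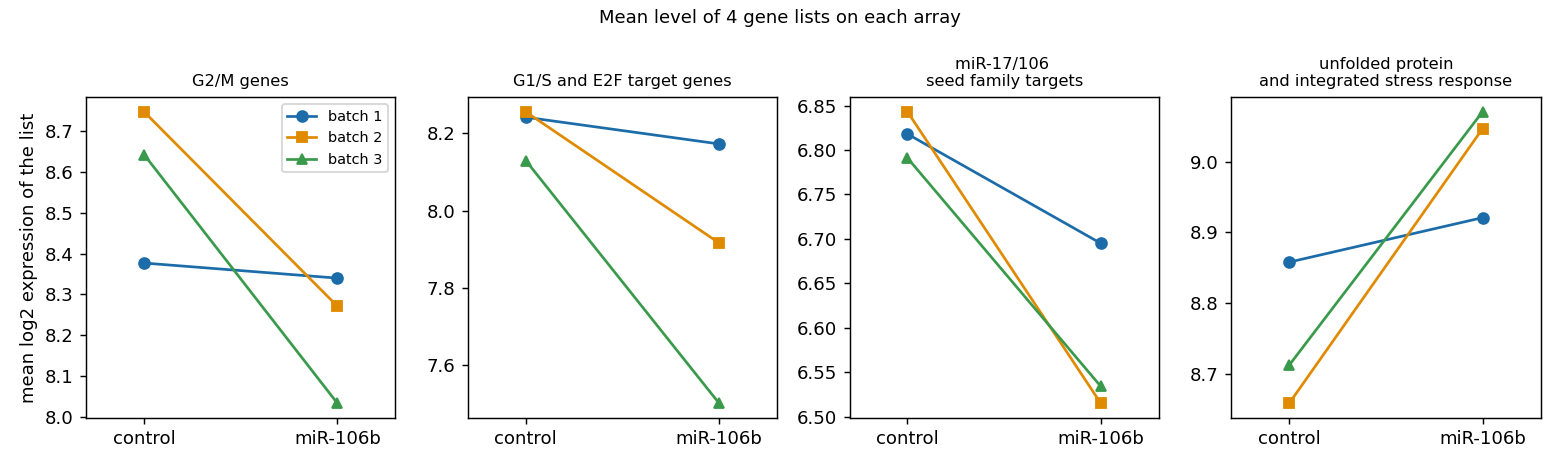
Mean log2 expression (vertical axis) of 4 gene lists on each of the 6 arrays, with a line joining the control and the pre-miR-106b array of a batch. In batch 1 the G2/M mean was 8.38 in control cells and 8.34 after pre-miR-106b, against 8.64 and 8.03 in batch 3.

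The focal adhesion list, taken from the theme of the series title and so not independent of the study's own choice, had 107 measured genes with a median difference of 0.00 (camera adjusted p = 0.921). Of these 56 were higher and 51 lower, and 0 passed over all genes or adjusted over the list alone. The laminin receptor subunit ITGA6 differed by 0.83 (SE 0.19), CTNNB1 (beta-catenin) by 0.57 (SE 0.15) and the small GTPase RAP1B by 0.52 (SE 0.13). CCND1, also a member, differed by -0.39 (SE 0.11). Caspases and apoptosis machinery had a median of 0.00 over 37 genes (adjusted p = 0.921), just below 0, with a mean and a test direction above it. DFFB, the apoptotic nuclease, rose when adjusted over the list alone (0.72, SE 0.15), 36 did not pass, and with the block 4 rose and 1 fell. PMAIP1 (0.49), BIRC2 (0.39) and BAK1 (0.38) passed over the list alone with the block and not without it, and BCL2L11 (-0.15) passed in neither. BCL2L11 was dim (3.87 in control cells), which limits what could be seen of a fall.

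Interferon-stimulated and double-stranded RNA response genes fell by a small amount (43 genes, median -0.09, camera adjusted p = 0.0233), with an adjusted p of 0.454 with an estimated correlation. Of its members 32 were lower and 0 passed adjusted over the list alone. OAS3 had a difference of -0.43 (SE 0.11) and EIF2AK2, which encodes the kinase PKR, of -0.33 (SE 0.11). Leaving out the pre-miR-106b array of batch 1 (adjusted p = 0.0982) or of batch 2 (0.114), or the control array of batch 3 (0.166), ended this call. The per-batch medians were -0.04, -0.13 and -0.15.

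Androgen-responsive genes did not pass without the block (36 genes, median 0.07, adjusted p = 0.0558) and were higher with it (adjusted p = 0.0094, or 0.640 with an estimated correlation). Both depended on the setting: over single arrays left out without the block the adjusted p ranged from 1.11e-04 to 0.740, and with the block it was 0.188 without batch 2. TSC22D3, the glucocorticoid-induced leucine zipper (0.69, SE 0.14, and 0.38 with a dimmer probe set), rose when adjusted over the list alone, and with the block 9 members rose and 2 fell. Batch medians were 0.13, 0.20 and 0.06. Cholesterol and lipid synthesis also had an adjusted p of 0.0558 (29 genes, median 0.09), which ranged from 0.00378 to 0.681 over single arrays left out. Its members HMGCS1 (0.48), IDI1 (0.48) and ACLY (0.40), enzymes that supply sterol and acetyl-CoA synthesis, rose when adjusted over the list alone, 26 did not pass, and with the block 6 rose.

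The remaining lists did not pass. Their camera adjusted p values were 0.176 for hypoxia and glycolysis (36 genes, median -0.06), 0.604 for neuroendocrine markers (7 genes, -0.01), 0.711 for microRNA machinery (17 genes, -0.04), and 0.813 for TGF-beta and BMP signalling (35 genes, -0.05), stromal and mesenchymal markers (12 genes, 0.08) and immediate early genes (27 genes, 0.02). They were 0.864 for p53 targets (24 genes, -0.03), oxidative phosphorylation (32 genes, 0.03) and ribosomal proteins (35 genes, 0.01), 0.921 for autophagy and lysosome (39 genes, 0.02) and 0.998 for luminal prostate markers (15 genes, median -0.01 and test direction below 0, mean 0.04). Within them, adjusted over the list alone, the glycolytic enzyme PFKP (0.499 times its control level) and the Argonaute AGO1 (-0.70) fell. ZMAT3, a p53 target, rose, and in the autophagy list FYCO1 fell and MAP1LC3B (0.50) rose. Adjusted over the list alone with the block, 2 p53 targets rose and 1 fell, 1 hypoxia gene rose and 1 fell, 1 immediate early gene rose and 1 fell, 2 autophagy genes rose and 1 fell, and 1 stromal marker rose. TGFBR2, a literature target, differed by -0.08 (SE 0.09). It was dim, at 3.07 in control cells against a 25th percentile of 5.02 to 5.07 on the arrays, which limits what could be seen of a fall. Basal epithelium markers (4 genes, median -0.02) and immune cell markers (3 genes, 0.15) had too few measured members for a test.

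**Figure D3:**
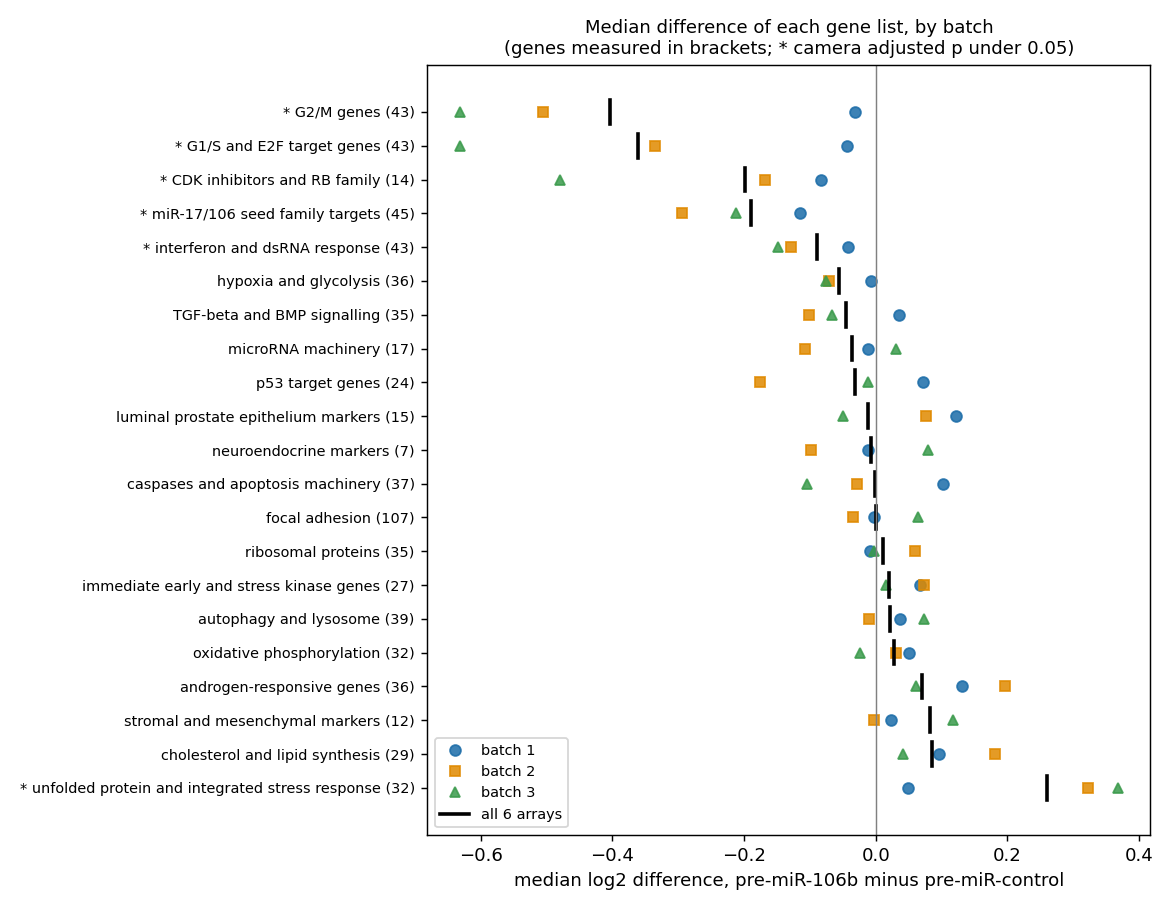
Median log2 difference (horizontal axis, pre-miR-106b minus pre-miR-control) of 21 gene lists, with 1 marker per batch, a bar for all 6 arrays and the number of measured genes in brackets. The G2/M and G1/S lists lie near 0 in batch 1 (-0.03 and -0.04) and at -0.63 in batch 3, and asterisks mark the 6 lists past the threshold without an estimated correlation.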

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

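The settings that combine the block with an adjusted p under 0.10, with an estimated correlation or with fry were chosen after seeing the data. For a gene list, values are camera adjusted p unless fry is named. The count of changed genes was 0 with 3 scalings, 2 filters on dim probe sets, mean probe sets, trend and robust options, all probe sets, and thresholds of 0.10 and 0.01. It was 8 with the replicate block, 85 with the block and the dimmest 25% of probe sets left out, 77 with the batch as a random effect, 421 with array weights, 982 at an unadjusted p under 0.05 and 395 with the block at an adjusted p under 0.10. At 1.5-fold it was 8, 63, 60 and 194 in the first 4 of these settings and 135 in the last, and 0 at 2-fold and with treat against 1.2-fold. Leaving out 1 array gave 0 to 95 genes in both counts, with 40 without the control array of batch 1, 95 without the pre-miR-106b array of batch 1 and 0 without any of the other 4. With the block and without 1 batch, the counts ranged from 0 (batch 2) to 340 (batch 1), or 292 at 1.5-fold, with 6 without batch 3. All 8 genes called with the block kept their sign without any 1 batch, which had to follow from their 1 sign in all 3 batches. Of the 8, 8 were called without batch 1, 0 without batch 2 and 6 without batch 3. The cause of these shifts was not tested.

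The 6 list calls were lost with an estimated correlation and with fry (0 lists in each, with and without the block). With an estimated correlation the adjusted p was 0.449 for the seed family and kinase inhibitor lists, 0.454 for the G2/M, stress and interferon lists and 0.623 for G1/S, and 0.640 for all 6 with the block. With fry it was 0.255 for the seed family, 0.256 for the kinase inhibitor and stress lists, 0.315 for G2/M, 0.340 for interferon and 0.453 for G1/S, and 0.327 for all 6 with the block. Camera's estimate takes the members' correlation across arrays into account, and that correlation was 0.609 in the G2/M list and 0.661 in the G1/S list. It was 0.193 in the stress list, 0.0816 in the seed family list, 0.0348 in the interferon list and 0.0221 in the kinase inhibitor list. The preset value was 0.01. The calls of lists with a lower correlation were lost too, so the loss was not confined to lists with a high correlation. Estimating the correlation also makes camera use the residual degrees of freedom of the 6 arrays, far fewer than with a preset value. The settings thus differ in more than the correlation, and what each part contributed to the loss was not tested. The interferon call was also lost with repeated quantile normalization (0.0503), and over single arrays left out its adjusted p ranged from 0.00318 to 0.166. With the block it was 0.0634 without batch 1 and 0.0728 without batch 2. The other 5 list calls held in every scaling, filter and left-out array or batch, but their medians moved. Over single arrays or batches left out these ranged from -0.499 to -0.158 for G1/S, from -0.580 to -0.289 for G2/M, from -0.378 to -0.0542 for the kinase inhibitor list, from -0.296 to -0.146 for the seed family and from 0.186 to 0.359 for the stress list. The androgen list passed without the block with centring on the 75th percentile (0.0378), with the dimmest 50% of probe sets left out (0.04998) and without 3 of the single arrays, and with the block it was lost without batch 2 (0.188). The cholesterol list passed with the same centring (0.0449) and filter (0.0261) and without 3 of the single arrays, and with the block it passed without batch 1 (0.0182) or batch 3 (0.0433). Among the 21 lists tested, the block alone changed the call of the androgen list only.

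No gene whose sign turned passed in a setting that turned it. With 1 array left out, RB1 ranged from -0.0626 to 0.102, VWF from -0.603 to 0.122, UCHL1 from -0.134 to 0.0421, ITGB4 from -0.0297 to 0.220 and NTS from -0.0429 to 0.227. The arrays that turned the sign were the pre-miR-106b array of batch 2 or the control array of batch 3 for RB1 and UCHL1, the pre-miR-106b array of batch 1 or the control array of batch 2 or 3 for VWF, and the pre-miR-106b array of batch 3 for ITGB4 and NTS. With the block, RB1 was at -0.0464 without batch 2, and without batch 3 RB1 was at -0.0255, BCL2L11 and UCHL1 at 0.0172 and DST at 0.0121. With mean probe sets RB1 was at -0.0784. Of 126 single genes run, 43 moved by over 1.5 times in at least 1 setting, 14 of them with mean probe sets, among which SAR1A was at 0.126, KLF9 at 0.303, TNPO3 at -0.198, MKRN1 at -0.262, TK2 at 0.261, ENTPD4 at 0.505 and ADAM17 at 0.415. The seed-site test, which was planned, was not run. Dim probe sets limit what can be seen, and no measure of background was used here.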

Other observations

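The 6 families in the first paragraph and the tests on batch 1, the poly-A controls and the stress arms were chosen after the results were seen. The COPII coat, which carries proteins out of the endoplasmic reticulum, was higher by camera (13 genes, median 0.23, adjusted p = 9.12e-04, and adjusted p = 0.230 with an estimated correlation). Adjusted over the list alone SEC24A (1.10), SEC24D (0.84), SEC24B (0.43) and SAR1A (0.42) rose and SEC23A (-0.46) fell, and with the block 6 rose and 1 fell. With mean probe sets SAR1A was at 0.13. Cytosolic aminoacyl-tRNA synthetases were higher (16 genes, 15 with higher values, median 0.18, adjusted p = 2.89e-05, and 0.117 with an estimated correlation), with CARS1 (0.51) and SARS1 (0.41) among the 5 that rose. Plasma membrane amino acid transporters were higher too (16 genes, median 0.27, adjusted p = 2.89e-05, and 0.0764 with an estimated correlation), with SLC7A5 (0.65) and SLC38A2 (0.50) among 5 that rose, or 7 with the block. Condensin and cohesin subunits were lower (17 genes, median -0.21, adjusted p = 5.74e-04, and 0.230 with an estimated correlation), and 0 passed adjusted over the list alone, with 5 lower with the block. Mitochondrial synthetases (adjusted p = 0.0835) and nuclear import and export receptors (0.0724) did not pass. Of the receptors KPNA2 (-0.65), KPNA5 (-0.56), XPO4 (-0.42) and TNPO3 (-0.37, or -0.20 with mean probe sets) fell adjusted over the list alone, with and without the block.

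The stress list had a median difference of 0.26, and its call was lost with an estimated correlation (adjusted p = 0.454). Whether folding genes of the endoplasmic reticulum carry the rise stays open. The amino acid and ATF4 arm (14 genes, median 0.41) lay above the folding arm (18 genes, 0.16) by 0.25, and in each batch (medians of 0.14, 0.53 and 0.51 against -0.01, 0.27 and 0.20). This decides nothing, because the arms were split after the top genes were known and the members' correlation (0.193) leaves no valid interval over genes. A general response of amino acid genes stays open too. Of the families of amino acid genes, cytosolic synthetases and transporters (2 of the 2 named for the test) were higher by camera, whereas 8 of 9 mitochondrial synthetases were lower (median -0.08). The 2 higher families were tested on the same arrays, share SLC7A11 and SLC3A2 with the stress list and lost the call with an estimated correlation. Amino acid supply in the medium was not tested.

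The cell-cycle lists lay near 0 in batch 1. A weaker response of every gene in that batch stays open. The slope of batch 1 on the mean of the other batches was 0.39 for 37 seed family targets. These lie outside the G2/M and G1/S lists and the list of cyclin-dependent kinase inhibitors and the retinoblastoma family. For the G2/M and G1/S genes (86 genes) the slope was 0.15. The gap of 0.24 decides nothing, because the cell-cycle genes were picked for lying near 0 in batch 1 and their correlation (0.609 and 0.661) leaves no valid interval over genes. The stress list also lay nearer 0 in batch 1 (0.05 against 0.32 and 0.37). A control array of batch 1 already low in G2/M genes may explain that list, with a level -0.32 against the mean of the other 2 control arrays. For G1/S genes the batch 1 control array lay 0.0488 above that mean, which argues against the same account there. Growth state of the batch 1 culture stays open as untested.

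Bacterial poly-A control transcripts were lower after pre-miR-106b in all 3 batches (24 probe sets, -0.21, -0.73 and -0.35, mean -0.43). The hybridization controls, added after labelling, were higher in batches 2 and 3 (by 0.56 and 0.26, 2 of these 2). In batch 1 they were lower too (-0.59, 0 of 18 higher). They cannot decide whether array brightness or hybridization lowered the poly-A controls in any batch. RMA had already equalized the arrays, and only the poly-A controls pass through labelling with the sample. The poly-A controls fell by less than the hybridization controls in batch 1, so the mean of -0.43 pools unlike batches. More polyadenylated RNA per unit of total RNA could give the lower poly-A values. It cannot be told apart from unequal addition of the controls. Both predict the same values, and no measure of the amount added was used here.

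The 6 arrays make 10 splits of 3 against 3, so no share under 0.05 can be reached. For genes changed, and for genes changed 1.5-fold, the real split and the highest other both gave 0, so that 10 of 10 splits gave as many. With the block, 1 of the 4 splits that part all 3 batch pairs gave as many genes as the real one, which is the real one itself, with 8 against a highest other of 0. For lists past the threshold 4 of 10 splits gave as many, with 6 against a highest other of 9, and the other 3 of these splits keep both arrays of batch 1 together and so follow a batch. With the block the 6 lists passed camera at the preset correlation, and 0 passed with an estimated correlation or with fry. The G2/M list had a median of 0.40 in size against a highest other of 0.36, the seed family targets 0.19 against 0.17 and the stress list 0.26 against 0.23, with 1 of 10 splits as large in each. For the G1/S list 2 of 10 were as large, with 0.36 against 0.39 in a split that also keeps batch 1 together. The highest other for the G2/M and stress lists came from the split that turns batch 1 around, the batch in which both lists lay nearest 0.

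Among probe sets outside the gene comparison, limma called 0 of 753 with several symbols (63 at an unadjusted p under 0.05), 0 of 1148 with no symbol (84) and 0 of 59 controls (9). With the block it called 0, 5 and 0, and 3 of these 5 were higher.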
